A study of Homo sapiens with 4 samples.

How the data were processed

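RNA from PK-1 and PK-9 clones with and without 4 days of tetracycline was labelled with Cy3 and hybridised to 1-colour Agilent arrays (design 026652), 1 array per sample. All 4 arrays lay on 1 slide and were scanned together, so slide and scan could not differ between groups. Per the file headers, the intensity values were made by Feature Extraction 10.7.3.1 with a 1-colour GE1 protocol, while the submitters' processing notes name Agilent Feature Extraction 9.5.1. The deposited processed signal is a spot's intensity after background subtraction and detrending within the array, with no scaling between arrays, per the file headers. The series' value table held the same numbers as this processed signal, with 0 differing cells, and its column medians were 146, 185, 158 and 141 in the order PK-1 without and with and PK-9 without and with tetracycline.

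Spots were 44495 per array. Control spots and spots flagged as non-uniform or as population outliers were left out: 345, 303, 421 and 504 gene spots on the arrays in that order. No spot was saturated. Processed signal was divided by the array's 75th percentile over gene spots (1628, 1875, 1638 and 1431), set to a floor of 0.01 and taken to log2. Scaling by a percentile assumes that this part of the distribution is alike between arrays, and the floor shortens the ratios of dim genes. Spots of 1 probe were averaged. The median SD of the 10 spots of 999 replicated probes was 0.0540, 0.0550, 0.0474 and 0.0514 log2, which covers error within an array only.

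Probes were named by transcript accession through the RefSeq table for GRCh38.p14, used for names only. Of 34127 probes, 25422 matched 1 symbol and 8705 did not. They gave 19483 symbols, of which 19455 had a usable probe. For the 4907 genes with several probes the brightest was used. Measured probes of 1 gene differed by a log2 of at least 1 in 128 of 3513 genes in PK-1 and 48 of 3478 in PK-9, and changed 2-fold in opposite directions in 1 and 0.

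Within a line, the log2 ratio was given with the standard error of the scanner's error model and without a test. A gene well above background on only 1 of the 2 arrays has a bound, the brighter value over the higher of the dim value and the lowest signal well above background. The same bound served the line comparison for genes not above background on either array of a line, and no fold is given where 1 of the 2 was above. The effect over both lines, and the line difference, came from limma 3.58.1 in R 4.3.3 (lmFit and eBayes, line plus tetracycline, Benjamini-Hochberg) on genes well above background on at least 2 of 4 arrays. Nothing in the labels says that the samples were repeated cultures, so the adjusted p-values measure only the spread between these arrays. Overlaps were tested with Fisher's exact test across genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the rest. Random lists were drawn 10000 times within 20 bins of mean signal.

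Named genes followed a rule fixed before the data were examined: LHX6, the 12 largest rises and falls and 4 largest bounds per direction in each line, the 12 largest per direction among genes changed 2-fold the same way, 4 per direction among opposite genes, 6 per direction for line and 4 members per list. The text gives a part of each. The 8 largest per direction among brighter genes in each line, the calls among brighter genes, and members of lists beyond the leading 4 were chosen after their values were seen.

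The steps were tested on simulated data with 200 changed genes. Over the 15571 genes, limma called 0 of 68 genes changed by a log2 of 0.8, 0 of 63 changed by 1 and 58 of 69 changed by 2, with 0 false calls. In it 9 unchanged genes, of the 14038 above background on all 4 arrays, were at least 2-fold different the same way in both lines. Over the 10880 brighter genes it called all of the 200, with 24 false calls among 224 and 0 unchanged genes 2-fold different the same way. That is above the nominal 5% and applies to a simulated spread that varied with signal only. The list percentile put 4 of 100 unshifted lists of 18 genes outside the middle 95% and 100 of 100 lists shifted by 0.5 above it. These lists were random draws from the same genes, so the share of 4 does not apply to lists whose members vary together.

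Alternatives were normexp background correction, quantile normalization, median scaling, the series value table, the mean of all probes, a floor of 0.05, genes above background on all 4 arrays, no filter, flagged spots kept, no block, a variance trend and each line alone. Mean spot signals are not in the columns used here, so normexp (offset 50) was run on median spot and background signals, without spots flagged for an uneven background. Brighter genes, genes brighter in each line (a mean of at least -3 in PK-1 and in PK-9), random lists matched on the signal of the line itself, leaving out each array in turn from the fold between lines, and leaving out spots with an uneven background were added after seeing the data. The simulation did not cover the genes brighter in each line.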

Results

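Gene expression was measured in PK-1 and PK-9, both established human pancreatic cancer lines, each carrying a construct from which tetracycline releases the transcription of FLAG-tagged LHX6. LHX6 is a LIM homeodomain transcription factor known for its part in the development of cortical interneurons. Each line was profiled once without the drug and once after 4 days of tetracycline, so that the 4 arrays formed 4 groups of 1 array. Every array carried 43118 gene spots for 34127 probes. Of these spots, 30753 were well above background in PK-1 without tetracycline, 36501 in PK-1 with it, 31235 in PK-9 without it and 30982 in PK-9 with it. The number of arrays limits the precision: a change within 1 line had no replicate check, and its error below (±) is the standard error that the scanner software's spot error model gives. Changes are log2 ratios of scaled signal with over without tetracycline, and no comparison here separates LHX6 from tetracycline itself.

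The 2 PK-1 arrays differed at their dim end. The 25th percentile of processed signal was 33.3 on the PK-1 array with tetracycline and 13.0 on the one without, against 15.2 and 14.2 for PK-9. Probes for olfactory receptors, a family with little expected expression in pancreatic cells, had a median signal of 25.3 on the PK-1 array with tetracycline and of 6.23, 7.38 and 6.22 on the PK-1 array without it and the PK-9 arrays without and with it. Over the 19455 named genes, the median log2 ratio in PK-1 reached 0.68 in the third decile of signal and was between -0.01 and 0.04 in the upper 5 deciles. For this reason 10880 brighter genes, those with a mean log2 scaled signal of at least -3, are also described separately, a division chosen after the data were seen.

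**Figure D1:**
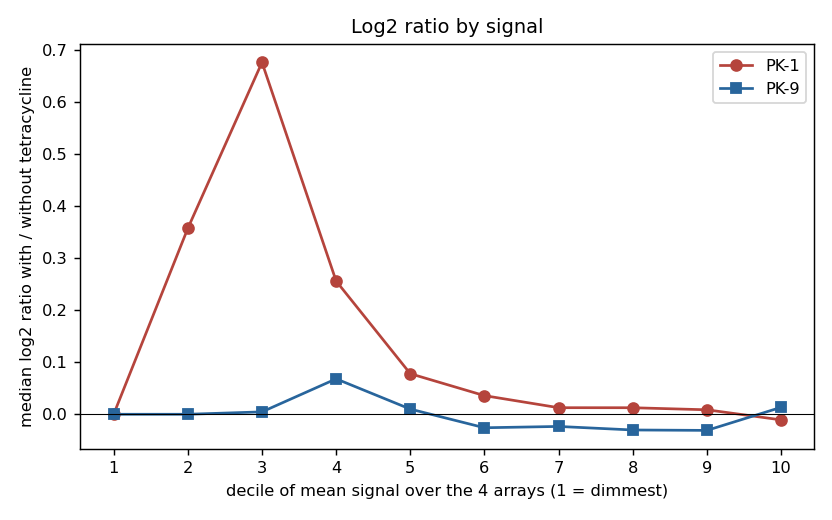
Median log2 ratio (with over without tetracycline, no unit) of named genes in each decile of mean signal, with 1 line per cell line. PK-1 reaches 0.68 in the third decile, while PK-9 stays between -0.03 and 0.07. The mean is over all 4 arrays, so genes raised from the floor on 1 array sort into higher deciles.

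The induced gene was examined first. A single named probe (NM_014368) represented LHX6. Its processed signal in PK-1 was 680.9 without and 575.6 with tetracycline, a log2 ratio of -0.45 ± 0.20. In PK-9 the signals were 9.34 and 7.83, and the probe was not well above background on either array. The array therefore showed no rise of LHX6 in either line. Where this probe lies relative to the part of the transcript in the construct is not given in the sources used here, so it does not check the labels, and "with tetracycline" below means the array labelled so.

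Which genes responded in both lines was asked first with a model of line and tetracycline. Over all 15571 genes tested it called 0 genes, and the 4 genes named next each had a limma adjusted p of 0.734. The adjusted p-values below come from the same fit over the brighter genes only, a division chosen after the data were seen. Among the brighter genes, MMP1 rose most: this interstitial collagenase was 4.73-fold higher in PK-1 and 4.09-fold higher in PK-9, with a mean log2 change of 2.14 ± 0.11 (SE) and a limma adjusted p of 3.19e-04. MGP, an inhibitor of calcification, rose by a mean log2 of 1.40 ± 0.10 (limma adjusted p = 0.0035), and SERPINA3, an acute-phase protease inhibitor, by 1.12 ± 0.10 (limma adjusted p = 0.0119). AGR2, a disulfide isomerase of mucus-secreting cells, fell by 1.08 ± 0.11 (limma adjusted p = 0.0124). Both lines showed the same direction for each of these 4 genes. The fit itself favours this, since its only residual is the difference between the lines' responses.

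In all, 46 of the 10880 brighter genes passed an adjusted p of 0.05, 32 of them higher and 14 lower with tetracycline. The risers included the cytokine IL32 (1.17 ± 0.14), the cytokine subunit EBI3 (0.96), the ubiquitin-like modifier UBD (1.03 ± 0.14), the amino acid oxidase IL4I1 (1.07) and the transcription factor BATF2 (0.73). They also included the ectonucleotidase NT5E (1.12 ± 0.15), the vitamin D hydroxylase CYP24A1 (1.10 ± 0.17), the lysosomal protein CD68 (1.05 ± 0.10), the WNT ligand WNT3 (0.93 ± 0.11), the WNT target SP5 (0.78 ± 0.10) and SNAI1 (0.89 ± 0.14), a repressor of E-cadherin. The genes that fell included the keratins KRT13 (-0.89 ± 0.10) and KRT15 (-0.66), PTHLH (-0.91 ± 0.11), which encodes parathyroid hormone-related protein, the aldehyde dehydrogenase ALDH3A1 (-0.88), the atypical cadherin FAT2 (-0.85), the chemokine receptor ACKR3 (-0.87 ± 0.11) and the ligand WNT4 (-0.77 ± 0.11). SAA1 and PTX3, both acute-phase genes, were among the calls although their probes were well above background on only 1 of the PK-1 arrays. Because the division used the mean of all 4 arrays, 9 of the 46 had a mean below -3 in PK-1 itself, among them IL32 (-3.83), IL4I1 (-4.40), EBI3 (-4.55) and WNT4 (-4.91), so the raised dim end of the PK-1 array reaches them. Of the 46, 35 lay at or above -3 in each line, and each of these was also among 67 calls over the 10310 genes that did, a subset likewise chosen after the data were seen.

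These calls depended on the division by signal. On simulated data the same fit over brighter genes made 24 false calls among 224, more than the adjusted p of 0.05 states. Over all 15571 genes tested, limma called 0 genes for tetracycline at an adjusted p of 0.05, with 995 at an unadjusted p under 0.05, a lowest adjusted p of 0.734 and 5 calls when the variance followed a trend with signal. The fit has 1 residual degree of freedom, which is the difference between the lines' responses.

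By size alone, 17 of the 14038 genes well above background on all 4 arrays changed at least 2-fold the same way in both lines, 16 higher and 1 lower. Independent lists of these lengths would share 2.32 higher genes (two-sided Fisher's exact test across genes, p = 9.44e-10) and 0.0695 lower genes (Fisher's exact p = 0.0672). These figures pool dim and bright genes. Rises of 2-fold were more frequent among the 8575 dimmer genes (440 in PK-1, 79 in PK-9) than among the 10880 brighter genes (35 and 28). Genes of like signal would thus share more than 2.32, and the p-value for higher genes overstates the overlap. Among brighter genes alone, 5 were higher in both lines, against 0.0871 expected. Genes are not independent replicates, and simulated data held 9 unchanged genes at this size in both lines among the same 14038. DKK4, a secreted WNT inhibitor, was the most strongly raised, at 2.35 ± 0.24 in PK-1 and 2.67 ± 0.24 in PK-9. The chemokine CXCL12 was at 2.21 ± 0.26 and 1.45 ± 0.23, the hexokinase-like HKDC1 at 1.66 ± 0.23 and 1.07 ± 0.22, the interleukin 7 receptor IL7R at 1.24 ± 0.30 and 1.18 ± 0.20, the sialic acid-binding receptor CD33 at 1.23 ± 0.31 and 1.45 ± 0.22, and the proteoglycan SPOCK1 at 1.20 ± 0.29 and 1.14 ± 0.23. CST2, DCANP1, PLA2G2D and the peptidase KLK7 were also at least 2-fold higher in both. The 1 gene lower in both was the noncoding LINC00636, at -1.41 ± 0.35 and -1.54 ± 0.21, named after its values were seen. Apart from MMP1, MGP, SERPINA3, CD68 and IL4I1, these 17 genes were dim. Quantile normalization gave 9 genes of this kind, 5 higher and 4 lower, so these are not all among the 17. Under normexp there were 4, all higher.

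Across the 14038 genes the log2 ratios of the lines correlated weakly (Pearson r = 0.18, Spearman rho = 0.19), a description over genes and not over samples. Among the brighter genes, r was 0.25 and rho 0.16, and quantile normalization gave r = 0.11. At a ratio of 1.5-fold, 115 of the 14038 genes were higher in both lines, 19 were lower in both and 42 went in opposite directions. Quantile normalization gave 46, 51 and 53, and the brighter genes alone 33, 16 and 5.

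**Figure D2:**
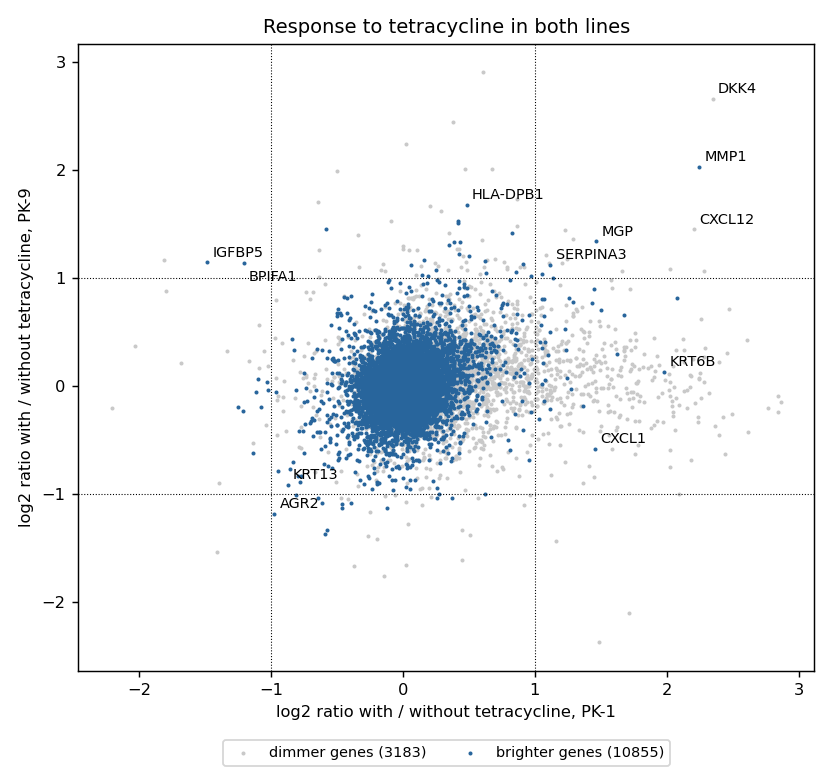
Log2 ratio with over without tetracycline in PK-1 (horizontal) and PK-9 (vertical), 1 point per gene well above background on all 4 arrays, with brighter genes in blue, dimmer genes in grey and dotted lines at 2-fold. MMP1 lies at 2.24 and 2.03, and the dimmer genes spread to the right along the PK-1 axis.

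In PK-1, the brighter genes were ranked, after the data were seen, by the rule used for all genes. The keratin KRT6B was higher with tetracycline (1.98 ± 0.21), as were PDZK1IP1 (2.08 ± 0.27), the type IV collagen gene COL4A1 (1.62 ± 0.22), the RAS effector RASSF2 (1.68 ± 0.21) and the neutrophil chemokine CXCL1 (1.46 ± 0.26). The corresponding PK-9 values were 0.13 for KRT6B, 0.82 for PDZK1IP1, 0.29 for COL4A1, 0.66 for RASSF2 and -0.58 for CXCL1. PDZK1IP1, COL4A1 and CXCL1 were bright in PK-9 but had mean log2 scaled signals of -4.49, -3.62 and -4.86 in PK-1, within the raised dim end of that array, whereas KRT6B (-1.89) and RASSF2 (-1.95) were above it. Lower genes included IGFBP5 (-1.49 ± 0.21), a carrier of insulin-like growth factors, the keratin KRT4 (-1.25 ± 0.20), ceruloplasmin CP (-1.21 ± 0.21), the calprotectin subunit S100A9 (-1.11 ± 0.20), the secretory proteins BPIFA1 (-1.21 ± 0.26) and SCGB1A1 (-1.10 ± 0.20), and RGS16 (-1.08 ± 0.20), which quenches G protein signals.

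Over all genes, 1345 were at least 2-fold different in PK-1. Of the 14687 measured on both arrays, 475 were higher and 54 lower, and a further 791 higher and 25 lower were bounds from a gene well above background on 1 array. The higher share was 94.1%, against 63.6% after quantile normalization and 81.1% under normexp. Quantile normalization gives all arrays 1 distribution, which removes a broad shift by construction. After it, 204 genes measured on both PK-1 arrays were higher and 211 lower, while the bounds were 219 higher and 31 lower. Most of the 1345 genes were dim: among brighter genes, 35 were higher and 10 lower. The 12 highest ratios, from 2.40 to 2.85, belonged to dim probes, such as those of the neuritin gene NRN1 (2.85 ± 0.34), the homeobox genes BARHL2 (2.84 ± 0.31) and ALX1 (2.77 ± 0.28), and the T cell receptor gene PTCRA (2.62 ± 0.31). The cell cycle inhibitor CDKN2B was at 2.44 ± 0.26 and WNT2B at 2.40 ± 0.23. The lowest ratios belonged to DCX (-3.18 ± 0.31), a neuronal microtubule protein, GAB4 (-2.57 ± 0.26) and KLK12 (-2.19 ± 0.29), likewise dim. As bounds, CD8B was at least 11.7-fold and CORIN at least 9.51-fold higher, and the gelatinase MMP2 at least 7.11-fold lower. The number of genes at least 2-fold different fell to 95 under normexp, 94 with a floor of 0.05 and 49 among brighter genes.

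In PK-9, the brighter genes were ranked in the same way. The class II antigen presentation genes HLA-DPB1 and HLA-DPA1 were at 1.68 ± 0.20 and 1.53 ± 0.20, against 0.48 ± 0.21 and 0.42 ± 0.22 in PK-1. The protease inhibitor CST6 was at 1.51 ± 0.21, NT5E at 1.42 ± 0.20 and the mitochondrial enzyme gene OGDHL at 1.34 ± 0.24. OGDHL was bright in PK-1 but had a mean log2 scaled signal of -4.41 in PK-9. The ribosomal RNA gene RNA18SN5 was at 1.45 ± 0.20 in PK-9 and -0.58 ± 0.20 in PK-1. Lower brighter genes were the epidermal differentiation factor ZNF750 (-1.38 ± 0.20), the cytochrome gene CYP2B6 (-1.34 ± 0.20), AGR2 (-1.19 ± 0.20), the growth factor carrier FGFBP1 (-1.13 ± 0.20), the sialyltransferase ST6GALNAC1 (-1.13 ± 0.20) and CSRNP1 (-1.10 ± 0.20).

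Over all genes, 319 were at least 2-fold different in PK-9. Of the 14582 measured on both arrays, 107 were higher and 52 lower, with 89 higher and 71 lower as bounds, so that 61.4% were higher (79.6% under normexp). The highest ratios were those of the NADPH oxidase NOX1 (2.91 ± 0.34), DKK4, the netrin receptor UNC5A (2.45 ± 0.30), MMP1 and the citrate transporter SLC13A5 (2.02 ± 0.34). The lowest were those of TCERG1L (-2.38 ± 0.35), the receptor phosphatase PTPRZ1 (-2.28 ± 0.32), the NODAL co-receptor CRIPTO (-2.11 ± 0.30), WNT8B (-2.58 ± 0.33) and the immediate early gene NR4A1 (-1.77 ± 0.25). All 12 lowest ratios, and all but 2 of the 12 highest, belonged to dim genes. The 2 were those of MMP1 and HLA-DPB1. As bounds, PRAMEF4 was at least 8.74-fold higher and UGT2B15, a steroid-conjugating enzyme, at least 6.74-fold lower, both likewise dim. The count was 54 under normexp, 63 with a floor of 0.05, 123 among genes above background on all 4 arrays and 43 among brighter genes.

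Gene lists fixed before the data were examined were set against 10000 random lists of the same size matched on signal, which describes these arrays and is not a test between conditions. NF-kB and cytokine genes had a median of 0.40 in PK-1, above every random list, and of -0.27 in PK-9, below every random list. In PK-1, 14 of 15 members had a ratio above 0, with CXCL1 at 1.46, CCL20 at 1.03, CXCL3 at 0.96, CXCL8 at 0.91 and TNFAIP3 at 0.90. In PK-9 these 5 genes were at -0.58, -0.31, -0.69, -0.41 and -0.14. All of these but TNFAIP3 had a mean log2 scaled signal below -3 in PK-1. Against random lists matched on PK-1 signal alone the list stood at the 99.98th percentile, and the 8 members at or above -3 in each line had medians of 0.33 in PK-1 and -0.12 in PK-9, the latter within the random range. Cholesterol synthesis genes had a median of -0.39 in PK-9, below every random list, with MSMO1 at -0.70, IDI1 at -0.69, LSS at -0.61 and HMGCS1 at -0.59, and 1 of 16 members had a ratio above 0. In PK-1 their median was 0.05. Basal-like pancreatic cancer genes had a median of -0.30 in PK-9, below every random list, with SERPINB4 at -1.23, SERPINB3 at -1.03 and KRT15 at -0.72, whereas CST6 was at 1.51. SERPINB3 and SERPINB4 were not well above background in PK-1. Their PK-1 median was 0.00.

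Hypoxia genes had medians of 0.13 in PK-1 (98.7th percentile) and -0.16 in PK-9 (0.44th), and among brighter genes the PK-1 median of 0.10 lay within the random range. Also low in PK-9 were ATF4 targets (-0.14, 0.17th) and TGF-beta targets (-0.18, 0.17th), with CCN2 at -0.54 in PK-1 and -0.76 in PK-9. Of the 16 TGF-beta members, 4 had a ratio above 0 in PK-9, and PMEPA1 rose by a mean log2 of 0.64 over both lines. Notch genes were low in PK-1 (-0.17, below every random list) and not in PK-9 (0.01, 57.4th, with 6 of 12 members above 0), with NRARP at -0.55 and -0.52 and HES1 at -0.56 and -0.31 in PK-1 and PK-9. Interferon-stimulated genes (0.13, 99.9th) and pancreatic duct markers (0.23, 99.7th) were high in PK-1, with the duct factor SOX9 at 0.49 and 0.91. Matched on PK-1 signal alone, the duct list was at the 96.3th percentile, within the middle 95%. Classical pancreatic cancer genes were high in PK-9 (0.22, 98.9th), although AGR2 fell in both lines and the 5 brighter members had medians of -0.26 in PK-1 and -0.0064 in PK-9. LIM genes and cofactors were also high in PK-9 (0.18, 98.6th), a position kept in 7 of 12 alternative settings. Among brighter genes their PK-9 median was 0.05, within the random range, and their PK-1 median of 0.15 was above it (98.0th). Among genes brighter in each line both medians were 0.18 and above the range. The interneuron list stood at 0.38 in PK-1 (97.8th), with 11 of 16 members above 0. The dim gene CUX2 was at 1.11, whereas the brighter gene ACKR3 fell in PK-1 and PK-9 (-0.95 and -0.79). The list was at the 95.9th percentile when matched on PK-1 signal alone and had a PK-1 median of 0.00 after quantile normalization. Over both lines, MAPK feedback genes were at the 99.4th percentile with a median of 0.10, and their 4 leading members went both ways, with DUSP5 at -0.48 and -0.66 and ETV4 at 0.29 and 0.76.

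The remaining lists lay within the middle 95% of random lists in both lines, but 2 of them lay near its edge. Epithelial junction genes in PK-9 were below the range in 7 of 12 alternative settings and housekeeping genes in PK-1 above it in 6 of 12, as well as when matched on PK-1 signal alone. Cell cycle genes had medians of 0.00 and 0.02, housekeeping genes 0.05 and 0.02, p53 targets 0.02 and -0.09, apoptosis regulators 0.04 and -0.04, unfolded protein response genes -0.03 and -0.04, WNT targets 0.01 and 0.04, epithelial junction genes 0.05 and -0.07, and mesenchymal genes 0.05 and 0.12. Among markers of other cell types, the medians were 0.66 and 0.03 for acinar, 0.44 and 0.16 for endocrine and 0.25 and 0.30 for fibroblast genes. Immune markers were the exception, at 0.79 in PK-1 (99.8th percentile) and -0.0047 in PK-9. Their PK-1 median was at the 99.94th percentile when matched on PK-1 signal alone and at the 93.1th after quantile normalization. Of the 10 measured immune markers, CD68 and CD79A were the 2 brighter genes, and CD79A was at 0.12 and 0.36. Over all genes tested, limma called 0 members of any list for tetracycline. Adjusted over the list alone, it called 1 classical gene and 1 immune marker.

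**Figure D3:**
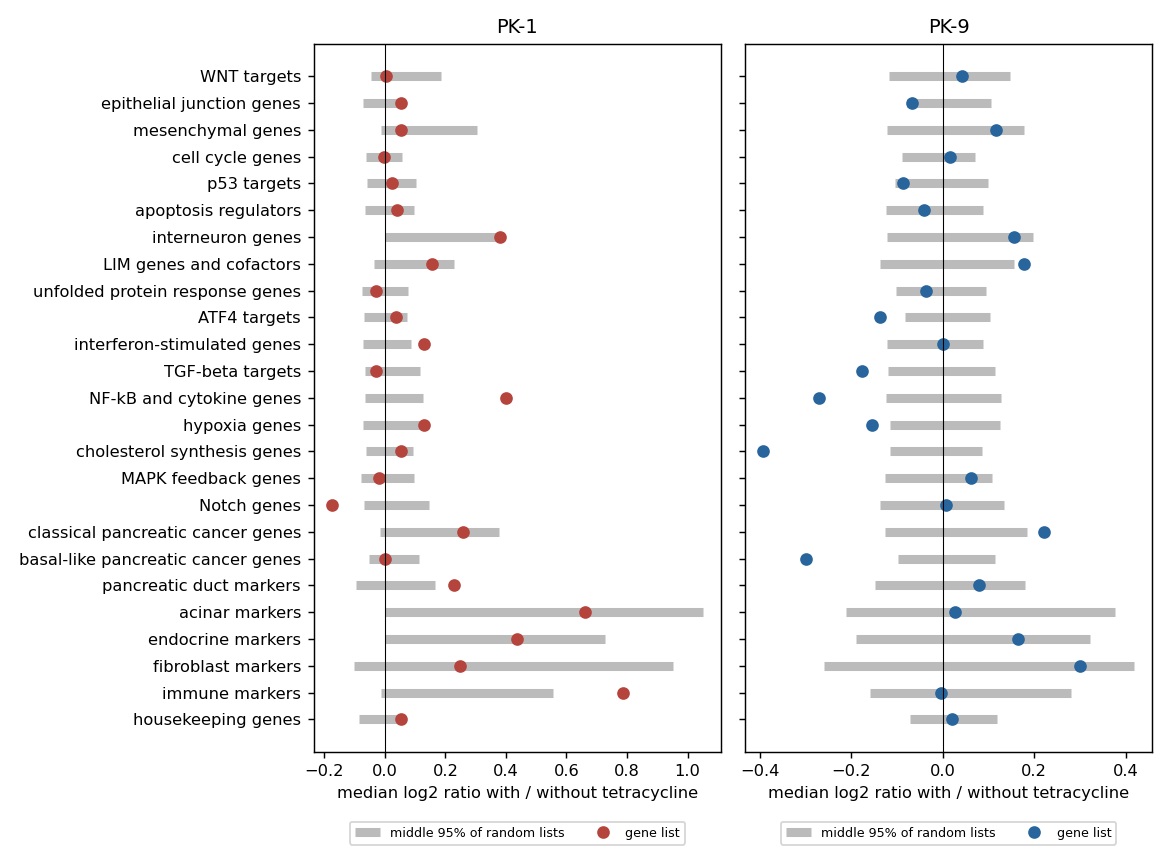
Median log2 ratio (with over without tetracycline) of each gene list in PK-1 (left) and PK-9 (right), as points, with grey bars for the middle 95% of 10000 random lists matched on signal. NF-kB and cytokine genes lie at 0.40 in PK-1 and -0.27 in PK-9.

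At least 2-fold different in opposite directions were 7 genes, against 17 the same way, and after quantile normalization there were 9 of each kind. Higher in PK-1 and lower in PK-9 were CRIPTO (1.72 ± 0.26 and -2.11 ± 0.30), TCERG1L (1.49 ± 0.34 and -2.38 ± 0.35), the small nucleolar RNA RNU105C (1.16 ± 0.36 and -1.44 ± 0.34) and FCRL2 (2.09 ± 0.27 in PK-1, and 2-fold lower in PK-9). Lower in PK-1 and higher in PK-9 were TNFSF8 (-1.81 ± 0.31 and 1.17 ± 0.38), IGFBP5 (-1.49 ± 0.21 and 1.15 ± 0.20) and BPIFA1 (-1.21 ± 0.26 and 1.14 ± 0.20). IGFBP5 and BPIFA1 were the only 2 of these 7 among the brighter genes, and both were below -3 in PK-1. With 1 array per condition, none of these differences was tested.

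The lines themselves differed far more than the treatment groups. In the same limma fit, 7073 of 15571 genes differed between lines at an adjusted p of 0.05, 3361 higher and 3712 lower in PK-9. The stem cell glycoprotein OLFM4 was at least 7527-fold and osteopontin SPP1 at least 5927-fold higher in PK-9, where PK-1 was not well above background (limma adjusted p = 0.0035 for both). The death receptor TNFRSF10B was at least 528.2-fold higher in PK-9 (limma adjusted p = 0.0035). CXCL1 was 1706-fold higher in PK-9 (limma adjusted p = 0.0069). Leaving out the PK-1 array with tetracycline, on which CXCL1 was brighter, gave 2827-fold, and leaving out the other PK-1 array gave 1029-fold. S100A8 and SAA2 were also higher there, with 1 of the PK-1 arrays above background. In PK-1, the superoxide dismutase SOD3 was at least 1339-fold higher, RAB34 at least 838.5-fold and ZNF22 at least 346.3-fold, while CRIP1 and ICAM2 were 368.5-fold and 313.1-fold higher (limma adjusted p = 0.0035 for each of these 5). The inflammasome adaptor PYCARD was also higher in PK-1, with 1 of the PK-9 arrays above background. Each line is 1 clone here, so these differences are between the clones. For OLFM4, SPP1, TNFRSF10B, SOD3, RAB34 and ZNF22, both arrays of the dimmer line sat at the floor. That line therefore gave no spread to their adjusted p-values.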

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

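All tests in this part except that of the other probes of genes with very bright spots were chosen after the result was seen.

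Signals outside the comparisons stood out on the PK-1 array with tetracycline. Among 15 probes for external spike-in RNAs that were dim without tetracycline, the median log2 ratio was 1.15 in PK-1 and -0.03 in PK-9, and 12 were higher in PK-1. Negative control spots did not share this, with a log2 ratio of -0.16 in PK-1, while olfactory receptor spots had 2.02 in PK-1 and -0.25 in PK-9. The dim genes that were higher in PK-1 thus moved with probes that match no cell RNA, which argues against genes switched on by the treatment as the whole cause. Non-specific hybridisation on that array goes with the spike-in median of 1.15. The negative controls had median signals of 3.73 and 3.33 in PK-1 and 3.81 and 3.79 in PK-9, without and with tetracycline. These are left after background subtraction within each array, so their lack of a rise cannot decide the question. A real rise of some dim genes stays open. Scaling by the 75th percentile is argued against, since 1 factor per array moves all genes alike. Dimmer genes above background on at least 1 PK-1 array lay 0.36 above brighter genes (bootstrap 95% interval over genes 0.343 to 0.374). More spots were above background on the array with tetracycline, so this filter favours genes that rose, and the interval carries that bias. The interval is over genes on 1 pair of arrays, so it does not measure the spread between arrays. Over all 8575 dimmer genes, those at the floor included, the gap was 0.13. Deciles of mean signal use no filter on background, but their mean includes the PK-1 array with tetracycline. The lowest decile held only genes at the floor, so genes that left the floor on that array sorted into higher ones. The third decile had a median of 0.68, against at most 0.04 in the upper 5, and carries that bias. Without any sorting, the 25th percentile of PK-1 processed signal was 33.3 with and 13.0 without tetracycline. The 75th percentile was 1875 and 1628. The bound for the gap was lowered from 0.5 to 0.1 after the value was seen.

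On the PK-9 array with tetracycline, 40 spots left out as non-uniform or outlying were at least 16-fold brighter than without it, a signal in data that the comparisons do not use. For the 11 genes with another usable probe, the other probes had a median log2 ratio of 0.00, and for the 7 of them above background it was 0.15, with 0.65 the highest. Spot defects are consistent with these values. No biological explanation was tested.

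Differences between the lines were noted where the ratio went opposite ways, and none was tested. PK-1 minus PK-9, the log2 ratios differed by 3.83 for CRIPTO, 3.86 for TCERG1L, 2.60 for RNU105C and 3.09 for FCRL2. The differences were -2.98 for TNFSF8, -2.63 for IGFBP5 and -2.35 for BPIFA1. The median of NF-kB and cytokine genes differed by 0.67 and that of hypoxia genes by 0.29, although the PK-1 median of hypoxia genes lay within the random range among brighter genes.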

How the results depend on the processing

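Brighter genes, genes brighter in each line, the variance trend within brighter genes, matching on the signal of the line itself, leaving out each array from the fold between lines, and leaving out spots with an uneven background were added after seeing the data. Genes at least 2-fold different in PK-1 numbered 1345, and 95 under normexp, 665 after quantile normalization, 94 with a floor of 0.05, 412 above background on all 4 arrays, 49 among brighter genes and 23 among genes brighter in each line. In PK-9 the 319 became 54 under normexp, 63 with the floor, 123 on all 4 arrays, 43 among brighter genes and 27 among those brighter in each line. The 17 changed the same way, 16 higher and 1 lower, became 4 under normexp and 9 after quantile normalization, 5 higher and 4 lower. The count was 5 with the floor, 52 with no filter, 5 among brighter genes and 3 among those brighter in each line. Single lines gave 123 (PK-9) to 412 (PK-1). limma calls for tetracycline went from 0 to 2 under normexp, 5 with a variance trend, 46 among brighter genes, 111 among these with the trend and 67 among genes brighter in each line. Line calls went from 7073 to 4183 with the floor and 2618 with no filter. The correlation of 0.18 became 0.11 after quantile normalization, 0.0924 with no filter, 0.25 among brighter genes and 0.241 among those brighter in each line. The number of lists outside the random range over both lines, 10, stayed between 7 and 10, and each line alone gave 7 and 8. The ratio of LHX6 in PK-1 stayed within its error wherever it was computed; it is not among the brighter genes. Among ratios of at least 2-fold and medians of lists outside the random range, directions turned for the log2 ratio of SH3RF3 in PK-9 (0.0864 under normexp) and the classical list in PK-9 (-0.0064 among brighter genes and those brighter in each line, where PK-1 went from 0.26 to -0.26). Of lists outside the random range over both lines, the median turned in 1 line for 5: NF-kB from 0.40 to -0.27, cholesterol synthesis from -0.39 to 0.0530, MAPK feedback from -0.0208 to 0.0618, Notch from -0.17 to 0.0070 and immune markers from 0.79 to -0.0047. Medians of lists within the random range turned in 26 further values of 15 lists, and 7 more lists over both lines turned in 1 line. Of the 12 alternative settings, the position outside the random range was kept in 7 for interneuron genes in PK-1, 10 for hypoxia in PK-1, 7 for LIM, 8 for classical and 11 for NF-kB genes in PK-9, and in 9 of 10 for immune markers in PK-1; the others kept it in all. Lists moved out of the range in PK-9 for epithelial junction (7), interneuron (3) and fibroblast genes (1 of 9), and in PK-1 for housekeeping (6), LIM (2), classical (2) and basal-like genes (1). Genes 2-fold different in opposite directions, 7, became 9 after quantile normalization and 30 with no filter. The all-array filter and brighter genes drop dim genes, where most 2-fold changes lay. Elsewhere no cause was tested. Of 4425 other values of named genes, 4089 stayed within their error, 335 moved further and 1 turned. The 46 calls kept their sign in every setting but the all-array filter and genes brighter in each line, where 44 and 35 were measured and kept it. The series value table changes nothing by construction. Matched on the signal of the line itself, 6 lists lay outside the random range in PK-1 and 8 in PK-9. Acinar, endocrine, fibroblast and immune lists had under 3 brighter members and gave no value. Slide or scan as a block was not run, since there was 1 of each. By replicate number, no paired analysis was possible because the groups share only the number 1. The fit pairs arrays by line, and without that block it called 0 genes for tetracycline. Signal over background limits the dim genes: 14038 of 19455 were well above background on all 4 arrays.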

Other observations

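The tests of the lists in this part were set before the members' values were seen, after the genes that led to them, and the tests on the PK-1 low end and ATF4 targets after.

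Class II antigen presentation genes other than HLA-DPA1 and HLA-DPB1 were also higher in PK-9. The 9 other genes had a median log2 ratio of 0.58, at the 99.98th percentile of random lists, with HLA-DQA1 at 1.18, HLA-DRA at 0.93, CD74 at 0.86, HLA-DRB1 at 0.76 and the class II activator CIITA at 0.50. HLA-DQA1 was not well above background in PK-1, where the median was 0.15, at the 51.2th percentile. The hypothesis that class II genes rise together in PK-9 was thus consistent with these arrays, with no replicate to test it. Of acute-phase and complement genes other than SERPINA3 and SAA1, 11 had a median of 0.33 over both lines, at the 99.92th percentile, with CFB at 0.82 and 0.52, LCN2 at 0.70 and 0.32 and HP at 0.44 and 1.10 in PK-1 and PK-9. Matched on PK-1 signal alone, their PK-1 median of 0.28 was at the 96.5th percentile, within the random range.

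In PK-9 the aldo-keto reductases AKR1C1 (-1.04 ± 0.20) and AKR1C3 (-0.94 ± 0.20) and the glutathione peroxidase GPX2 (-0.91 ± 0.20) were lower. They are known NRF2 targets or their relatives, and near-identical AKR1C transcripts can share a probe. The hypothesis that NRF2 targets fall there was not borne out: 16 others had a median of -0.07, at the 15.1th percentile, within the random range. Only 5 of the 16 had a ratio above 0, among them GCLC at 0.42.

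The genes that rose in both lines were weighed against 3 explanations. For brighter genes, the raised low end of the PK-1 array is argued against as the whole cause. The 35 brighter genes at least 2-fold higher in PK-1 had a median of 0.50 in PK-9, above the random range of -0.11 to 0.07. Of these, 29 were above 0 in PK-9. Of the 17 such genes brighter in each line, 16 were above 0, with a median of 0.66. Dim genes that rose in both lines, such as DKK4 and CXCL12, were not covered by this test. An ATF4 response to tetracycline is argued against by ATF4 targets, whose larger median of the 2 lines was 0.0377. The other split within lines called 0 brighter genes against 46, but only 1 of 2 splits calls as many, too few splits for a share under 0.05. Other effects of tetracycline and an effect of LHX6 may both account for the 46 calls and cannot be separated, since arrays of tetracycline without the construct were not analysed here. With 1 array per group, differences between cultures and false calls stay open as well. The LHX6 probe itself showed no rise in either line.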
